A study of Arabidopsis thaliana with 21 samples.

How the data were processed

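Total RNA from whole 7-day-old Arabidopsis seedlings grown in liquid medium was extracted with TRIzol, cleaned on columns and made into TruSeq libraries, per the labels' protocols. Each of the 21 libraries belongs to the wild type (Col) or to 1 of 6 transgenic lines, and every one of these 7 groups has 3 libraries. The labels name the lines NEET10-10, NEET11-9, NEET5-4, H89C11-7, H89C23-10 and H89C4-7. The title of the series ties H89C to a dominant-negative form of the iron-sulfur protein AtNEET; the labels give no promoter, tag or insertion site.

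The deposited file is 1 table of 32833 genes by 21 libraries, and its unit is a normalized signal, gene counts that the authors divided by 1 size factor per library. Per the submitters' processing notes, the tools were FastQC 0.11.7, STAR 2.4.0.1 and DESeq2 1.20.0, with the TAIR10 genome. The read counter, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, such as the LHCB1, LHCB2 and RBCS genes of photosynthesis and the SESA and cruciferin genes of seeds, may therefore hold reads that were split between copies, and overlapping or antisense genes cannot be told apart. The step between the lowest values of each library gave the size factors back, and 100% of the values became whole reads within a tolerance of 0.001. Recovered totals ran from 8.24 M to 24.68 mega (M) reads per library with a median of 21.16 M. No column of the table was left unused. Gene symbols came from the reference annotation, TAIR10.1, in which 32548 of the genes were found. The file had been taken for normalized values when the design was written, and the test named there for that case was used.

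Values were analysed as log2(normalized count + 1), so a log2 change understates the change of genes with few reads. Genes with a normalized count of at least 10 in at least 3 libraries were tested, which kept 20699 genes. The main test was limma-trend (limma 3.58.1 in R 4.3.3) with 1 mean per group, a spread shared by all 21 libraries and 14 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05 with no limit on its fold change. Each line was compared with Col. The mean of the 3 H89C lines and the mean of the 3 NEET lines were each compared with Col in the same fit, and genes called in the same direction in all 3 lines of a construct were counted. H89C was compared with NEET on 1 mean per line, 3 lines against 3, by limma on those 6 values.

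The labels do not say whether the 3 libraries of a line came from separate cultures. The p-values and standard errors (SE) against Col therefore measure the spread between these libraries, which may be technical, and not the spread between independent plants of a genotype. For the mean of a construct against Col they also leave out the spread between its 3 lines. Lines of 1 construct differed more than libraries of 1 line: the median standard deviation was 0.221 between line means and 0.119 between libraries on the log2 scale. No pair of replicates agreed within sampling noise. A chi-square per degree of freedom between replicates ran from 1.46 for Col 2 and 3 to 16.7 for Col 1 and 2, and it was 12.26 for NEET10-10 1 and 2, so the first library of Col and that of NEET10-10 stood apart from the other libraries of their groups.

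A set of 20 gene lists with 358 entries was fixed before the data were examined, as were the tests, the filter, the alternatives except those named as added, and the rule for named genes. The lists cover iron deficiency, iron storage, iron-sulfur cluster assembly in plastids and in mitochondria and cytosol, iron-sulfur and iron proteins, photosystems with antenna and Rubisco, chlorophyll synthesis, oxidative stress, salicylic acid and defence, jasmonate, sulfate assimilation, zinc and copper deficiency, anthocyanin, carbon starvation, abscisic acid and drought, heat shock, seed storage, root hair and endodermis, the circadian clock and reference genes. Members called were counted over all tested genes and adjusted over the list alone. Each list was tested against the other genes by limma's camera with a preset correlation of 0.01 between genes, and again with an estimated correlation. Camera p-values were adjusted over the 20 lists of a comparison.

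The genes named are AtNEET; in each comparison the 5 with the largest rise and the 5 with the largest fall among called genes with a mean normalized count of at least 50 in the higher group and every transgenic library beyond every Col library (between constructs, every line mean beyond those of the other construct); up to 4 members of each list with the smallest adjusted p; and 12 iron genes fixed by name. Any other gene named was chosen after its values were seen, and the text says so.

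Because all comparisons share the 3 Col libraries, changes of unchanged groups against those libraries were simulated 20 times to give the correlation and covariance that shared controls alone produce. The controls could not be split, since each part would need at least 2 libraries. Alternatives were other pseudocounts, other filters, TMM scaling, a limit on the fold change, the replicate number as a block, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered reads, leaving out each library and each line, and the line as a random block. Added after the data were seen were the iron list without H89C11-7, the NEET results without NEET11-9, the removal of trends on gene length and GC content, thinning of every library to 8.24 M reads, the list counts without each library or line, and camera tests of every list without NEET11-9 and of the difference between 2 lines of a construct.

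The test was checked on simulated reads drawn from the real means and depths, with 200 genes changed. For the comparison of H89C11-7 with Col over 20699 genes it recovered 70.1% of the genes changed 1.5-fold, 89.6% of those changed 2-fold and 97% of those changed 4-fold, and 24 of its 195 calls (12.3%) were false. For the mean of the H89C lines the shares were 76.1%, 92.5% and 100%, with 33 false calls of 212 (15.6%). False calls in these simulations thus exceeded the nominal 5%. For the comparison of 3 lines with 3 lines they were 32.8%, 88.1% and 100%, with 7 false calls of 154 (4.5%). The shares against Col hold for simulated counts whose spread resembles that between libraries and say nothing of differences between lines. In the comparison of lines with lines a random spread between lines, equal for every gene, was added. Its shares hold only for that assumed spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.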

Results

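RNA was sequenced from whole Arabidopsis thaliana seedlings of the wild type Col and of 6 transgenic lines named after AtNEET (AT5G51720), the plant member of the NEET family of proteins that carry an iron-sulfur cluster. There were 3 libraries per line, so 9 libraries from 3 NEET lines, 9 from 3 H89C lines and 3 from Col. The name H89C denotes a change of histidine to cysteine at residue 89 of the protein. The title of the series calls the product dominant-negative and asks about iron-sulfur metabolism and iron homeostasis. Library depth lay between 17.88 and 24.68 mega (M) reads except in Col replicate 3, which had 8.24 M. Reads fell on 26740 genes in at least 1 library, and 20699 genes were tested.

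AtNEET itself lies on chromosome 5 at 21009347 to 21010345 of TAIR10.1, on the plus strand, and encodes 108 residues. Residue 89 is histidine, and its codon CAT occupies 21010165 to 21010167 in exon 2 of 2. Col held a normalized count of 261 ± 93.9 (SD, n = 3). The level was 16100 ± 895 in H89C4-7, 2380 ± 110 in H89C11-7 and 1299 ± 74 in H89C23-10, which are rises of 63.9-fold, 9.46-fold and 5.16-fold on the log2(value + 1) scale. Among the NEET lines it was 32840 ± 1900 in NEET10-10 and 18190 ± 528 in NEET5-4, rises of 130-fold and 72.3-fold. NEET11-9 had 332 ± 5.78, only 1.32-fold above Col (limma adjusted p = 0.0404), and all 3 of its libraries lay within the range of the Col libraries, 186 to 367. Transgene and endogenous transcripts were counted together, and the H89C codon cannot be read from gene counts.

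**Figure D1:**
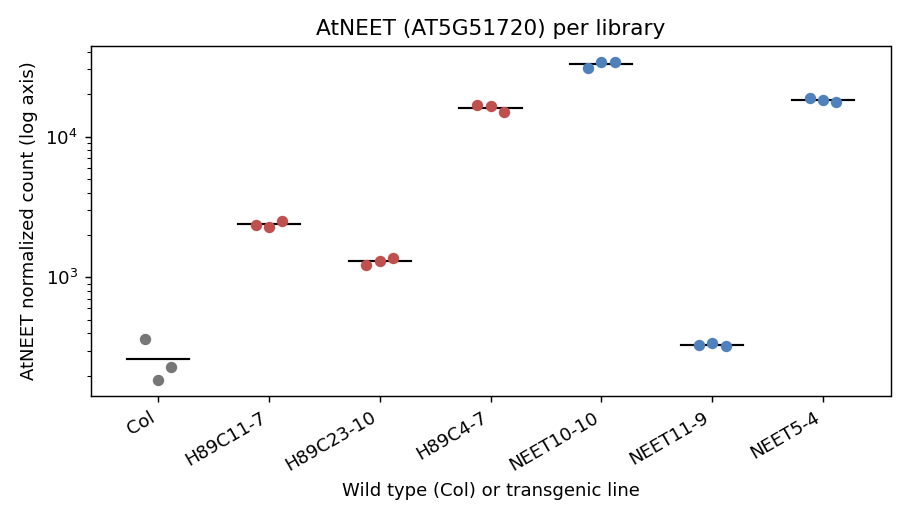
Normalized AtNEET count of each library on a log axis, by wild type and line, with the line mean as a bar. The 3 libraries of NEET11-9 lie at the level of Col, while those of the other 5 lines lie above every Col library.

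The lines differed widely in how much of the transcriptome moved against Col. H89C4-7 had 13783 genes called by limma, 6955 higher and 6828 lower, which is 66.6% of the genes tested. H89C11-7 had 7813 (4105 higher, 3708 lower) and H89C23-10 had 4568 (2390 higher, 2178 lower). NEET5-4 had 6418 (2923 higher, 3495 lower), NEET10-10 had 6277 (3232 higher, 3045 lower) and NEET11-9 had 2261 (929 higher, 1332 lower). Most changes were small: with a limit of 2-fold the counts were 3286 in H89C4-7, 865 in H89C11-7, 289 in H89C23-10, 816 in NEET5-4, 387 in NEET10-10 and 327 in NEET11-9. The count for NEET11-9 fell to 1370 without its replicate 2 and to 1467 and 1505 without its replicates 1 and 3.

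**Figure D2:**
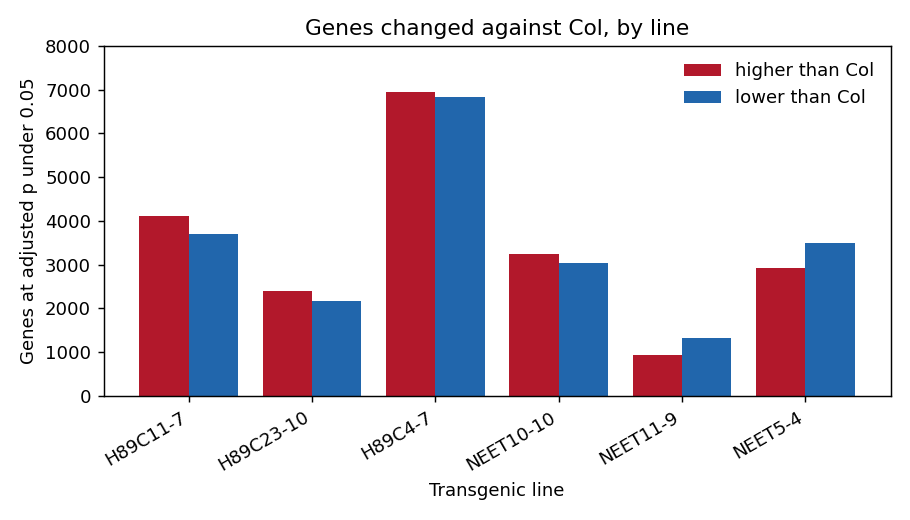
Number of genes per line at a limma adjusted p under 0.05, higher than Col (red) and lower than Col (blue). H89C4-7 has 6955 higher and 6828 lower genes, and NEET11-9 the fewest, 929 and 1332.

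The H89C lines were compared with Col to ask what the dominant-negative form does to the seedling transcriptome. Averaged over the 3 H89C lines, the nuclear genes of photosynthetic light harvesting were lower than in Col, sugar-starvation genes and heat shock proteins were higher, and genes for iron-sulfur cluster assembly were slightly higher. With an estimated correlation camera no longer called the photosystem list (adjusted p = 0.134) or the plastid (0.0781) and the mitochondrial and cytosolic (0.0509) assembly lists. The iron deficiency genes did not move together, since 23 of 36 rose in H89C11-7 while 15 fell and 1 rose in H89C23-10. Large changes were ranked among called genes with a mean of at least 50 in the higher group and every H89C library beyond every Col library. Within these limits the largest rise was in AT2G33160, a polygalacturonase gene. It went from 1.31 ± 1.15 in Col to 22.6 ± 4.7, 10.6 ± 4.39 and 355 ± 21.5 in H89C11-7, H89C23-10 and H89C4-7 (log2 4.45 ± 0.39 SE, limma adjusted p = 8.2e-10). Within the same limits AtNEET followed (log2 3.87 ± 0.10, adjusted p = 3.37e-19). The beta-glucosidase gene DIN2, a classic marker of darkness and sugar starvation, rose from 304 ± 33 to 1602 ± 240, 628 ± 44.9 and 14760 ± 742 in the same order (log2 3.01 ± 0.12, adjusted p = 2.24e-16). AIG1, a gene induced in pathogen resistance, rose by log2 3.14 ± 0.31 and PLP4, a patatin-related phospholipase, by log2 2.85 ± 0.24.

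Among the largest falls within these limits was AGL44, also called ANR1, a MADS-box regulator of root responses to nitrate. It dropped from 72.8 ± 9.23 in Col to 11.6 ± 1.28, 6.58 ± 0.362 and 3.37 ± 1.24 in H89C11-7, H89C23-10 and H89C4-7 (log2 -3.31 ± 0.18, limma adjusted p = 1.79e-13), while the 3 NEET lines held 75.7 to 106. The fatty acid desaturase gene ADS1 fell by log2 -2.51 ± 0.11, FTM1, another desaturase, by log2 -2.25 ± 0.21, and the cold and drought gene COR15A by log2 -2.24 ± 0.06 (adjusted p = 6.13e-19). The non-coding RNA AT2G01422 fell by log2 -3.65 ± 0.40, from 91.9 ± 11.2 to 2.66 ± 1.94 in H89C4-7. By the rule of the ranking, all 9 H89C libraries lay beyond all 3 Col libraries in these 9 genes and in AtNEET.

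Of 36 measured iron deficiency genes, 14 rose and 10 fell in the mean of the H89C lines, counted over all genes or adjusted over the list alone, and camera found no shift (adjusted p = 0.568; median log2 -0.03, mean 0.03). The lines disagreed. H89C11-7 had 23 members up and 4 down (camera adjusted p = 2.64e-09, and adjusted p = 0.00118 with an estimated correlation), H89C23-10 had 1 up and 15 down (camera adjusted p = 9.54e-05, but adjusted p = 0.0527 with an estimated correlation), and H89C4-7 had 10 up and 16 down. Without H89C11-7 the mean gave 6 up and 18 down, and without H89C4-7 6 fell. The clade Ib bHLH regulators, which switch on iron uptake, show the split. In H89C11-7 bHLH38 rose by log2 1.21, bHLH39 by 1.13, bHLH100 by 1.57 and bHLH101 by 1.16. In H89C23-10 bHLH38 fell by log2 -0.92, bHLH100 by -0.76 and bHLH101 by -0.74. Their means over the 3 lines were log2 -0.18 for bHLH38, 0.13 for bHLH39, 0.23 for bHLH100 and -0.09 for bHLH101. Of these only bHLH100 was called (limma adjusted p = 0.0287), and it was not without Col replicate 1 (adjusted p = 0.203) or Col replicate 3 (0.114) and turned to log2 -0.435 without H89C11-7.

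BTS, an iron-binding ubiquitin ligase that restrains the iron deficiency response, rose in the H89C mean by log2 0.63 ± 0.04 (limma adjusted p = 7.1e-13), with a 2.15-fold rise in H89C11-7, log2 0.74 in H89C4-7 and 0.04 in H89C23-10. Its neighbour in that network, PYE, rose by log2 0.71 ± 0.05, the vacuolar iron exporter NRAMP4 by log2 0.57 ± 0.05 and the signalling peptide gene IMA1 by log2 0.53 ± 0.14, the last called only with H89C11-7 in the mean (log2 0.22, adjusted p = 0.249 without it). The nicotianamine synthase NAS1 fell by log2 -0.78 ± 0.07, with log2 -0.47, -0.26 and -1.61 in H89C11-7, H89C23-10 and H89C4-7. Root hair and endodermis markers fell in the same seedlings, 11, 0 and 12 of 14 in that line order. The root iron transporter IRT1 fell by log2 -0.44 ± 0.11 (adjusted p = 0.00246), most in H89C23-10 at log2 -1.12, and was not called without that line (log2 -0.10, adjusted p = 0.498). FIT at log2 -0.12 ± 0.10 and the ferric reductase FRO2 at log2 -0.13 ± 0.10 did not pass the test. Ferritin genes rose: FER1 by log2 0.54 ± 0.04, FER4 by log2 0.42 ± 0.07 and FER3 by log2 0.36 ± 0.07, 3 of the 4 risers among 10 measured iron storage genes, none of which fell (camera adjusted p = 0.16, adjusted p = 0.399 with an estimated correlation). FER1 rose in H89C4-7, from 2139 ± 126 to 8105 ± 223 (log2 1.92 ± 0.05), but was 2021 ± 46.3 in H89C11-7 and 1845 ± 51.2 in H89C23-10, and the mean without H89C4-7 turned to log2 -0.15. Without that line the storage list had 2 members up and 2 down. The fourth riser, VTL5 (log2 0.20 ± 0.07), was not called without Col replicate 2 (adjusted p = 0.0727) or 3 (adjusted p = 0.0664) or without H89C4-7 (adjusted p = 0.124).

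**Figure D3:**
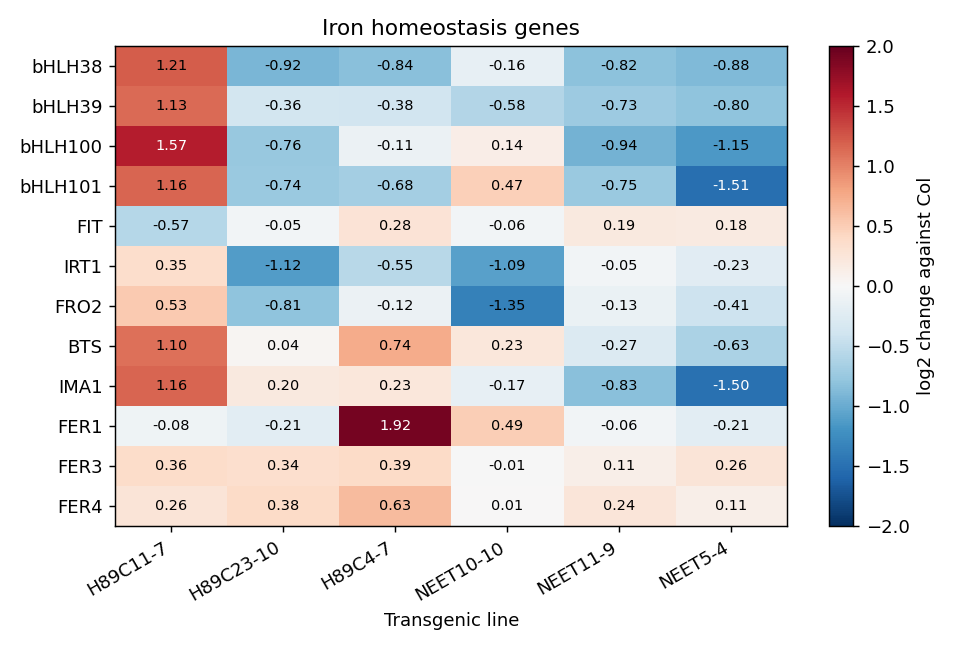
Log2 change against Col of 12 iron homeostasis genes in the 6 lines, red for higher and blue for lower. The 4 bHLH genes at the top are higher in H89C11-7 and lower in NEET11-9, and FER1 stands out in H89C4-7 at 1.92.

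Iron-sulfur cluster assembly genes were shifted upward in the H89C mean. In plastids 8 of 13 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0208, but adjusted p = 0.0781 with an estimated correlation). Among them SUFB, the scaffold subunit, rose by log2 0.50 ± 0.03, SUFE2 by log2 0.68 ± 0.08 and GRXS16 by log2 0.44 ± 0.06, while GRXS14 fell by log2 -0.30 ± 0.04. In mitochondria and cytosol 9 of 17 rose and 0 fell, with 9 and 0 adjusted over the list alone (camera adjusted p = 0.00964; adjusted p = 0.0509 with an estimated correlation). Of these 17 genes 9 had an unadjusted p under 0.05, and all 9 were rises. These included DRE2 by log2 0.65 ± 0.06, MET18 by log2 0.37 ± 0.05, the cysteine desulfurase NFS1 by log2 0.26 ± 0.04 and the mitochondrial exporter ABCB25 by log2 0.26 ± 0.05. Both shifts were largest in H89C4-7, where 10 of 13 and 12 of 17 members rose with medians of log2 0.33 and 0.40 (adjusted p = 0.0254 and 0.0155 with an estimated correlation). In H89C23-10 the medians were log2 0.04 and -0.03, with 5 up and 1 down in plastids and 2 up and 0 down in mitochondria and cytosol (camera adjusted p = 0.303 and 0.701). H89C11-7 had 4 up and 3 down in plastids and 7 up and 0 down in mitochondria and cytosol (0.392 and 0.0885). Without H89C4-7 5 members of each list were up. Reference genes moved in H89C4-7 too, with 5 of 8 up, 1 down and a median of log2 0.23 (camera adjusted p = 0.145). Of 26 iron-sulfur and iron proteins 16 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00381; adjusted p = 0.0929 with an estimated correlation). In H89C11-7 this list showed no shift, with 8 up and 5 down (median log2 0.02, camera adjusted p = 0.392). H89C23-10 had 12 up and 2 down and H89C4-7 16 up and 3 down (adjusted p = 0.0527 and 0.159 with an estimated correlation). TIC55 rose by log2 0.44 ± 0.04, the leaf-type ferredoxin FD1 by log2 0.36 ± 0.04 and nitrite reductase NIR1 by log2 0.33 ± 0.04, while CAO, the oxygenase that makes chlorophyll b, fell by log2 -0.46 ± 0.03 (limma adjusted p = 5.79e-11).

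Photosystem, antenna and Rubisco genes fell more uniformly. Of 42 nuclear genes for photosystems, antenna and Rubisco, 34 fell and 2 rose (36 and 3 adjusted over the list alone), with a median of log2 -0.37, and 24 of them fell in all 3 H89C lines. Camera gave an adjusted p of 5.49e-13 and, with an estimated correlation, an adjusted p of 0.134. The antenna genes led: LHCB3 went from 64460 ± 9150 in Col to 29030 ± 1950, 36860 ± 1410 and 29840 ± 2000 in H89C11-7, H89C23-10 and H89C4-7 (log2 -1.01 ± 0.06, limma adjusted p = 9.66e-13). LHCB2.2 fell by log2 -0.89 ± 0.05, LHCB1.1 by log2 -0.80 ± 0.04 and LHCB1.2 by log2 -0.78 ± 0.05. The 2 risers were the Rubisco small subunit genes RBCS1B at log2 0.38 and RBCS2B at log2 0.23, chosen for mention after their values were seen. In chlorophyll synthesis 12 of 23 genes fell and 3 rose (the same counts adjusted over the list alone; camera adjusted p = 0.00809, adjusted p = 0.129 with an estimated correlation). By line 11 fell and 1 rose in H89C11-7, 6 fell and 4 rose in H89C23-10, and 12 fell and 5 rose in H89C4-7. Camera called only H89C11-7 (adjusted p = 7.29e-04, 0.345 and 0.0793 in that order), and 4 genes fell in all 3 lines. The protochlorophyllide reductase PORA fell from 99.9 ± 9.82 to 27.7 ± 5.37, 55.6 ± 10.5 and 7 ± 5.5 in the same line order. PORC fell by log2 -0.45 ± 0.04. PORB fell by log2 -0.57 ± 0.04, a change carried by H89C4-7 at log2 -1.76 (0.02 without that line).

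Carbon starvation and senescence genes rose, 7 of 8 with 0 falling (8 and 0 adjusted over the list alone; camera adjusted p = 2.84e-06, and adjusted p = 0.0022 with an estimated correlation). Besides DIN2, SEN1 rose by log2 1.04 ± 0.04, NYC1, which starts chlorophyll b breakdown, by log2 0.93 ± 0.04 and DIN10 by log2 0.63 ± 0.04. These SE leave out the spread between lines. Over the 3 H89C line means the levels were 12100 ± 12400, 5510 ± 3060 and 19300 ± 7540 (SD) in that order. By line 5 rose and 1 fell in H89C11-7 (median log2 0.48), 8 rose and 0 fell in H89C4-7 (1.52), and 2 rose and 2 fell in H89C23-10 (0.09, camera adjusted p = 0.948). Without H89C4-7 1 fell in the mean. Of 8 heat shock genes 7 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 5.23e-04, adjusted p = 0.0317 with an estimated correlation). HSP90.1 went from 796 ± 56.8 to 1278 ± 69.1, 1155 ± 20 and 3870 ± 53.8. HSP70-4 rose by log2 1.02 ± 0.05, HSP101 by log2 0.95 ± 0.07 and HSFA7A by log2 0.51 ± 0.08. Of the heat shock list 7 rose in H89C11-7 and 7 in H89C4-7 (camera adjusted p = 0.0249 and 0.0254 with an estimated correlation). In H89C23-10 3 rose (adjusted p = 0.0654 with an estimated correlation). The member that fell, HSP18.2, was not called without Col replicate 3, H89C11-7 replicate 3, H89C23-10 replicate 3, line H89C11-7 or line H89C4-7, which left 0 falling. Abscisic acid and drought genes mostly fell, 11 of 15 with 2 rising, also adjusted over the list alone (camera adjusted p = 8.01e-04, adjusted p = 0.0906 with an estimated correlation). Examples are the proline synthesis gene P5CS1 at log2 -0.84 ± 0.04 and the abscisic acid synthesis gene NCED3 at log2 -1.09 ± 0.08, whereas LTI30 rose by log2 0.52 ± 0.06. This list had 9 down and 3 up in H89C11-7 and 10 down and 3 up in H89C4-7. In H89C23-10 it had 5 down and 1 up (median log2 -0.02, camera adjusted p = 0.217).

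Defence genes again split the H89C lines. In the mean 6 of 17 salicylic acid genes rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.166). In H89C11-7 16 of 17 rose (camera adjusted p = 3.15e-09, adjusted p = 2.54e-04 with an estimated correlation), whereas in H89C4-7 3 rose and 9 fell (camera adjusted p = 0.0874). H89C11-7 exceeded H89C4-7 by a median of log2 1.89 over the list (camera adjusted p = 3.89e-06, adjusted p = 0.0012 with an estimated correlation). Without H89C4-7 the mean gave 12 up and 0 down, and without H89C11-7 6 fell. ACD6 rose in each line, by log2 1.44, 1.27 and 0.64 in H89C11-7, H89C23-10 and H89C4-7. PR2 rose from 1.63 ± 2.83 to 36.4 ± 6.36, 6.61 ± 1.95 and 5.18 ± 3.23. SARD1 rose by log2 1.01 ± 0.16 in the mean and NPR1 by log2 0.40 ± 0.04. Oxidative stress genes went both ways, 9 up and 5 down of 21, also adjusted over the list alone (camera adjusted p = 0.216; median log2 0.12, mean -0.01). NAC013 rose by log2 0.84 ± 0.07, while OM66 fell by log2 -0.80 ± 0.08. ZAT12, up by log2 0.79 ± 0.08, and CAT1, up by log2 0.51 ± 0.05, were called only with H89C4-7 in the mean (log2 0.15 and 0.11 without it). Without H89C11-7 3 members of this list fell. Among 10 jasmonate genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.17). VSP1 was up by log2 1.01 ± 0.08, AOC1 up by log2 0.59 ± 0.05 and VSP2 down by log2 -1.05 ± 0.06; 3 rose without Col replicate 1 or H89C11-7 replicate 2.

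Markers of seed and root tissue moved as well. Of 12 seed storage and embryo genes 6 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.16). The albumin gene SESA2 went from 0.655 ± 0.574 to 33 ± 13.6, 23.5 ± 18 and 40 ± 21.2 (log2 4.17 ± 0.47). SESA3 rose by log2 3.55 ± 0.47 and the glyoxylate cycle gene ICL by log2 1.37 ± 0.09, while PER1 fell by log2 -0.80 ± 0.11. Of 14 root hair and endodermis genes 12 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.246 with an estimated correlation). Examples are TIP2;3 at log2 -1.71 ± 0.14, EXPA18 at -0.85 ± 0.13, PER64 at -0.70 ± 0.11 and PER3 at -0.57 ± 0.07. The root falls sat in H89C11-7 (11 of 14) and H89C4-7 (12 of 14), against 0 in H89C23-10, where 2 rose. Without H89C4-7 the mean gave 7. Clock genes had 6 of 11 up and 2 down (camera adjusted p = 0.16), and in H89C4-7 9 of 11 were up (adjusted p = 0.00349 with an estimated correlation). TOC1 rose by log2 0.72 ± 0.04, PRR5 by log2 0.54 ± 0.05 and LUX by log2 0.50 ± 0.04, while CCA1 fell by log2 -0.29 ± 0.04, although its mean was log2 0.01 without H89C23-10. The same 6 and 2 were called adjusted over the list alone; without H89C23-10 0 fell and without H89C4-7 5 fell.

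Camera called none of 4 further lists in the H89C mean. Sulfate genes had 4 up and 5 down of 17 (4 and 6 adjusted over the list alone; camera adjusted p = 0.489). APR3 was up by log2 0.38 ± 0.04 and SULTR2;1 down by log2 -0.53 ± 0.06, with 1 down without H89C4-7 or 8 down without H89C11-7. Zinc and copper genes had 2 up and 4 down of 13, also adjusted over the list alone (camera adjusted p = 0.619), led by FRO4 at log2 -0.78 ± 0.14; 2 fell without Col replicate 1, 4 rose and 2 fell without H89C4-7, and 1 rose without Col replicate 2 or 3, H89C11-7 replicate 3 or H89C4-7 replicate 1. Anthocyanin genes had 1 up (CHI, log2 0.25 ± 0.07) and 1 down (LDOX) of 8 (camera adjusted p = 0.944; median log2 0.02, mean -0.13). CHI lost its call without H89C4-7 (log2 0.17, adjusted p = 0.0875), which left 0 up and 2 down, and without H89C11-7 the list had 3 up and 0 down. LDOX lost its call without any of the 3 Col libraries, H89C23-10 replicate 2, H89C4-7 replicate 1 or line H89C11-7 (0 falling) and is not called adjusted over the list alone, which gave 1 up and 0 down. Reference genes had 2 up and 1 down of 8 (2 and 0 adjusted over the list alone; camera adjusted p = 0.489). ACT2 at log2 0.32 ± 0.04 and UBQ10 at log2 0.14 ± 0.04 rose, the second not called without Col replicate 2 (adjusted p = 0.0711) or H89C4-7 (adjusted p = 0.285).

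The mean of the H89C lines differed from Col in 10313 genes (5378 higher, 4935 lower; limma). In all 3 lines 1962 genes changed the same way (1077 higher, 885 lower). Independent lists of these sizes would share 159.3 and 128.7, which leaves out the shared Col libraries. Unchanged groups simulated against the same controls shared 0 on average, but groups without changes give almost no calls, so that 0 was fixed in advance. Neither value shows how many shared calls the Col libraries add, and a feature common to all 3 Col libraries is not in the simulation. A fit with the line as a random block used a single correlation for all genes (0.73). Its degrees of freedom came from libraries, so it is not a test on 3 line values. Col is a single block there, and the spread between lines comes from the transgenic lines alone. In this fit limma called 9 genes (1627 at an unadjusted p under 0.05). Among them were LHCB2.2 and its close copy LHCB2.3 at log2 -1.09, AGL44, the sucrose synthase SUS4 at log2 -1.76, the arginine decarboxylase ADC2 at log2 0.96 and the thalianol-pathway enzyme CYP708A2 at log2 1.41. All but LHCB2.2 and AGL44 were picked out after the result was seen.

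The NEET lines were compared with Col to describe the lines named after the unaltered protein, of which NEET11-9 had AtNEET within the range of Col. The mean of the 3 NEET lines showed lower iron deficiency, defence, oxidative stress, heat shock and anthocyanin genes and, as in the H89C lines, lower light-harvesting genes. With an estimated correlation the light-harvesting call was lost in both constructs (camera adjusted p = 0.0717 in NEET and 0.134 in H89C). Lines departed from the mean: in NEET10-10 7 defence genes rose and 3 fell, and in NEET11-9 1 heat shock gene rose and 0 fell. Without NEET11-9 all 6 lists were called with an estimated correlation (camera adjusted p = 0.00237, 0.0158, 0.0102, 0.0113, 0.0198 and 0.0496 in the order named). Among the 5 largest falls, ranked within the same limits for the NEET libraries, CYP82C2, a cytochrome P450 of indole defence compounds, had 154 ± 18.6 in Col, 55.8 ± 8.75 in NEET10-10, 0.272 ± 0.471 in NEET11-9 and 0 in every NEET5-4 library (limma adjusted p = 3.17e-16). AT5G38910, a cupin gene, went from 107 ± 6.06 to 48.5 ± 9.44, 1.95 ± 1.28 and 0 in the same order, and the berberine-bridge enzyme gene AT1G26390 from 666 ± 133 to 354 ± 44.6, 15.7 ± 3.14 and 4.74 ± 4.79. AT4G12500, a lipid-transfer protein gene, fell by log2 -3.76 ± 0.30. The non-coding RNA AT2G01422, low in the H89C lines too, fell by log2 -4.92 ± 0.40, to 0.967 ± 1.02, 1.67 ± 1.45 and 6.32 ± 4.46.

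Rises over the NEET lines within those limits were smaller. MRN1, which makes the triterpene marneral, went from 22.9 ± 2.06 to 186 ± 43.6, 118 ± 13 and 152 ± 8.91 in NEET10-10, NEET11-9 and NEET5-4 (log2 2.65 ± 0.15, limma adjusted p = 1.43e-12), and it was 105 ± 13.2, 426 ± 50.3 and 77.1 ± 26.5 in the H89C lines. The bHLH gene AT4G37850 rose by log2 2.01 ± 0.25, the stearoyl-ACP desaturase gene AT3G02620 by log2 1.99 ± 0.13, AT1G66800, a Rossmann-fold oxidoreductase gene, by log2 1.51 ± 0.14 and the vacuolar processing enzyme gene DELTA-VPE 2.47-fold. By the rule of the ranking, all 9 NEET libraries lay beyond all 3 Col libraries in these 10 genes. AtNEET was higher by log2 4.53 ± 0.10 in the mean, but not in each library, because of NEET11-9.

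Iron deficiency genes fell in the NEET lines. Of 36 measured, 24 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 7.46e-12, adjusted p = 6.69e-04 with an estimated correlation). The counts were 24 falling and 2 rising in NEET5-4, 15 and 0 in NEET11-9, and 13 and 5 in NEET10-10, and without NEET5-4 the mean gave 15 falling. The coumarin synthesis enzyme F6H1 fell by log2 -1.16 ± 0.10, the signalling peptide genes IMA3 by log2 -1.07 ± 0.07 and IMA1 by log2 -0.83 ± 0.14, and ORG1 by log2 -0.39 ± 0.04. The F6H1 level was 674 ± 704 (SD over the 3 NEET line means), so its mean fall does not describe each line. All 4 clade Ib bHLH genes fell in the mean: bHLH39 by log2 -0.70 ± 0.08 (limma adjusted p = 1.75e-07), bHLH100 by log2 -0.65 ± 0.09, bHLH38 by log2 -0.62 ± 0.12 and bHLH101 by log2 -0.60 ± 0.08. The last was not called without NEET5-4 (log2 -0.14, adjusted p = 0.221). Only bHLH39 fell in each line; in NEET10-10, the line with the most AtNEET, bHLH101 rose by log2 0.47 (adjusted p = 8.32e-04), and bHLH100 at log2 0.14 and bHLH38 at log2 -0.16 did not pass. FRO2 fell by log2 -0.63 ± 0.10 and BTS by log2 -0.22 ± 0.04, the latter not called without NEET5-4 (log2 -0.02). IRT1 fell by log2 -0.46 ± 0.11 and lost its call without Col replicate 1 (log2 -0.34, adjusted p = 0.0519) or without NEET10-10 (log2 -0.14, adjusted p = 0.285). FIT at log2 0.11 ± 0.10, FER1 at log2 0.08 ± 0.04, FER3 at log2 0.12 ± 0.07 and FER4 at log2 0.12 ± 0.07 did not pass. In the iron storage list 3 of 10 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.882; median log2 0.10, mean -0.08; 4 members at an unadjusted p under 0.05). They were VTL5 at log2 -0.32 ± 0.07, NAS3 at log2 -0.99 ± 0.23 and YSL1 at log2 -0.44 ± 0.11, the last not called without Col replicate 1 (adjusted p = 0.0624) and VTL5 not without NEET10-10 (log2 -0.15, adjusted p = 0.144). Without Col replicate 1 3 storage genes rose.

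Few iron-sulfur genes were called in the NEET mean. In the plastid assembly list 3 of 13 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.0344, adjusted p = 0.0677 with an estimated correlation). They were GRXS14 at log2 -0.37 ± 0.04, SUFE2 at log2 -0.41 ± 0.08 and NFU1 at log2 -0.27 ± 0.07, of which SUFE2 was not called without NEET5-4 (log2 -0.16, adjusted p = 0.184). The count was 6 without NEET11-9 (camera adjusted p = 0.00603, adjusted p = 0.0229 with an estimated correlation), and 5 fell without Col replicate 2 or 3. In mitochondria and cytosol 2 of 17 fell and 1 rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.775); 0 fell without Col replicate 1, which ends the call of ISU1 (log2 -0.06), as does leaving out NEET10-10 (adjusted p = 0.056) or NEET5-4 (adjusted p = 0.0515). Of 26 iron-sulfur and iron proteins 8 fell and 2 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0344, adjusted p = 0.167 with an estimated correlation), 1 rising without Col replicate 3. Without NEET11-9 that list had adjusted p = 0.0309 with an estimated correlation. FD1 fell by log2 -0.39 ± 0.04 and CAO by log2 -0.34 ± 0.03, while the thiamine synthesis gene THIC rose by log2 0.16 ± 0.03, a call lost without NEET11-9 (log2 0.06, adjusted p = 0.244).

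Light-harvesting genes fell in the NEET lines too. Of 42 photosystem, antenna and Rubisco genes 34 fell and 0 rose in the NEET mean (36 and 0 adjusted over the list alone), with a median of log2 -0.26, a camera adjusted p of 2.64e-17 and, with an estimated correlation, an adjusted p of 0.0717. By line 41 fell in NEET10-10, 23 in NEET5-4 and 9 in NEET11-9. LHCB2.1 fell by log2 -0.57 ± 0.06, LHCB2.2 by log2 -0.49 ± 0.05 and LHCB1.2 by log2 -0.49 ± 0.05 (limma adjusted p = 1.91e-07, 3.71e-08 and 7.24e-08). Chlorophyll synthesis had 12 of 23 falling and 0 rising (13 and 0 adjusted over the list alone; camera adjusted p = 3.65e-07, adjusted p = 0.00655 with an estimated correlation). These include the magnesium chelatase subunit CHLH at log2 -0.32 ± 0.04, PORC at log2 -0.34 ± 0.04 and HEME1 at log2 -0.28 ± 0.04. Anthocyanin genes fell in 5 of 8 cases with 0 rising (6 and 0 adjusted over the list alone; camera adjusted p = 0.00111, adjusted p = 0.0229 with an estimated correlation). Chalcone synthase CHS fell by log2 -0.52 ± 0.06 and DFR by log2 -1.35 ± 0.31. Of the list 3 fell without Col replicate 3 and 2 without NEET5-4.

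Salicylic acid and defence genes fell, 11 of 17 with 3 rising, also adjusted over the list alone (camera adjusted p = 1.09e-04, adjusted p = 0.00389 with an estimated correlation). By line 10 fell and 2 rose in NEET5-4, 8 fell and 1 rose in NEET11-9, whose AtNEET level was near that of Col, and 3 fell and 7 rose in NEET10-10 (median log2 0.16). In the mean 7 fell without Col replicate 3 or without NEET5-4. CBP60G, a regulator of salicylic acid synthesis, went from 995 ± 39 to 153 ± 8.84 in NEET11-9 and 124 ± 7.58 in NEET5-4 but to 1544 ± 19.6 in NEET10-10. PBS3 went from 308 ± 13.9 to 181 ± 14.4, 28.4 ± 5.11 and 16.4 ± 7.93 in NEET10-10, NEET11-9 and NEET5-4, and FMO1 from 116 ± 12.2 to 130 ± 21, 10.6 ± 4 and 2.6 ± 0.469. PAD4 fell by log2 -0.44 ± 0.07 in the mean, and by less, log2 -0.08, without NEET5-4, where it was not called (adjusted p = 0.459). Oxidative stress genes fell in 12 of 21 cases with 1 rising, also adjusted over the list alone (camera adjusted p = 4.71e-05, adjusted p = 0.00255 with an estimated correlation). The falls and rises were 16 and 0 in NEET5-4, 8 and 1 in NEET11-9, and 6 and 7 in NEET10-10 (median log2 -0.01). Without NEET5-4 5 fell in the mean. The ascorbate peroxidase APX2 went from 29.5 ± 6.34 to 1.25 ± 1.1, 1.96 ± 1.28 and 0.329 ± 0.57, and was 0 in the libraries of H89C11-7 and H89C23-10. ZAT12 fell by log2 -0.75 ± 0.08, CSD2 by log2 -0.30 ± 0.03 and the alternative oxidase AOX1D by log2 -2.69 ± 0.36. Of 8 heat shock genes 6 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 8.35e-04, adjusted p = 0.0212 with an estimated correlation). In NEET5-4 6 fell and 0 rose, in NEET10-10 5 fell and 1 rose, and in NEET11-9 0 fell and 1 rose (median log2 0.08). HSP70-4 was at log2 -0.76 ± 0.05, HSP90.1 at -0.49 ± 0.05 and HSP101 at -0.35 ± 0.07; 3 fell without Col replicate 3 or without NEET10-10.

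In the sulfate, carbon starvation, abscisic acid and clock lists NEET lines differed, with a camera test of the difference at adjusted p = 0.0035 or less with an estimated correlation in at least 1 pair of lines each. Sulfate assimilation genes had 8 of 17 up and 3 down (8 and 4 adjusted over the list alone; camera adjusted p = 0.0871), but the rises belonged to NEET10-10, where 10 rose (adjusted p = 6.52e-04 with an estimated correlation), and 0 rose in the mean without it. Without NEET11-9 the list was called (adjusted p = 0.0478 with an estimated correlation). SHM7 went from 1143 ± 124 to 3849 ± 102 in that line, against 1185 ± 54.5 in NEET11-9 and 1078 ± 49.6 in NEET5-4. The mean gave 5 rises without Col replicate 1, Col replicate 2 or NEET11-9 replicate 3, and 1 fall without Col replicate 1. Jasmonate genes had 6 of 10 up and 0 down, also adjusted over the list alone (camera adjusted p = 0.00602, adjusted p = 0.167 with an estimated correlation). No pair of NEET lines differed in this list by camera (adjusted p of 0.153 or more). AOC1 was at log2 0.41 ± 0.05 and OPR3 at log2 0.24 ± 0.05. Carbon starvation genes went both ways, 4 up and 3 down of 8, also adjusted over the list alone (camera adjusted p = 0.124; median log2 0.09, mean -0.25). ASN1 rose by log2 0.74 ± 0.04 and DIN10 by log2 0.64 ± 0.04, while DIN2 fell by log2 -1.48 ± 0.12. Abscisic acid genes had 5 up and 7 down of 15, also adjusted over the list alone (camera adjusted p = 0.493; median log2 0.02, mean -0.03). COR47 was up by log2 0.35 ± 0.06 and RD22 down by log2 -0.33 ± 0.04, and without NEET5-4 they were 10 up and 1 down. Clock genes had 4 up and 6 down of 11, also adjusted over the list alone (camera adjusted p = 0.0871), with PRR9 down by log2 -1.41 ± 0.12 and TOC1 up by log2 0.50 ± 0.04. In NEET5-4 8 of 11 were down and 2 up (median log2 -0.41, adjusted p = 0.00452 with an estimated correlation), opposite to H89C4-7; NEET10-10 had 5 down and 4 up and NEET11-9 3 down and 5 up. Without NEET11-9 the clock list was called lower in the mean (adjusted p = 0.0423 with an estimated correlation).

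Seed storage genes had 5 of 12 up and 1 down in the NEET mean, also adjusted over the list alone (camera adjusted p = 0.118; median log2 0.12, mean -0.05). MLS was up by log2 0.64 ± 0.09 and PER1 up by log2 0.71 ± 0.11; 3 rose without NEET5-4 and 2 fell without Col replicate 3. Root markers had 2 of 14 up and 1 down (4 and 1 adjusted over the list alone; camera adjusted p = 0.0871), and the count of rises ran from 0 without Col replicate 3 to 5 without Col replicate 2. Zinc and copper genes had 1 up, YSL2 at log2 0.22 ± 0.05, and 0 down of 13, also adjusted over the list alone (camera adjusted p = 0.574), with 2 up without Col replicate 1 or without NEET10-10. Without NEET11-9 YSL2 was not called (log2 0.07, adjusted p = 0.378), which left 0 up and 1 down. In the NEET mean, list counts of 0 to 2 moved by up to 3 when single libraries or lines were left out. Reference genes had ACT2 up by log2 0.19 ± 0.04 and GAPC2 down by log2 -0.36 ± 0.05 of 8, also adjusted over the list alone (camera adjusted p = 0.775); 2 rose without Col replicate 2 and 2 fell without Col replicate 1.

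**Figure D4:**
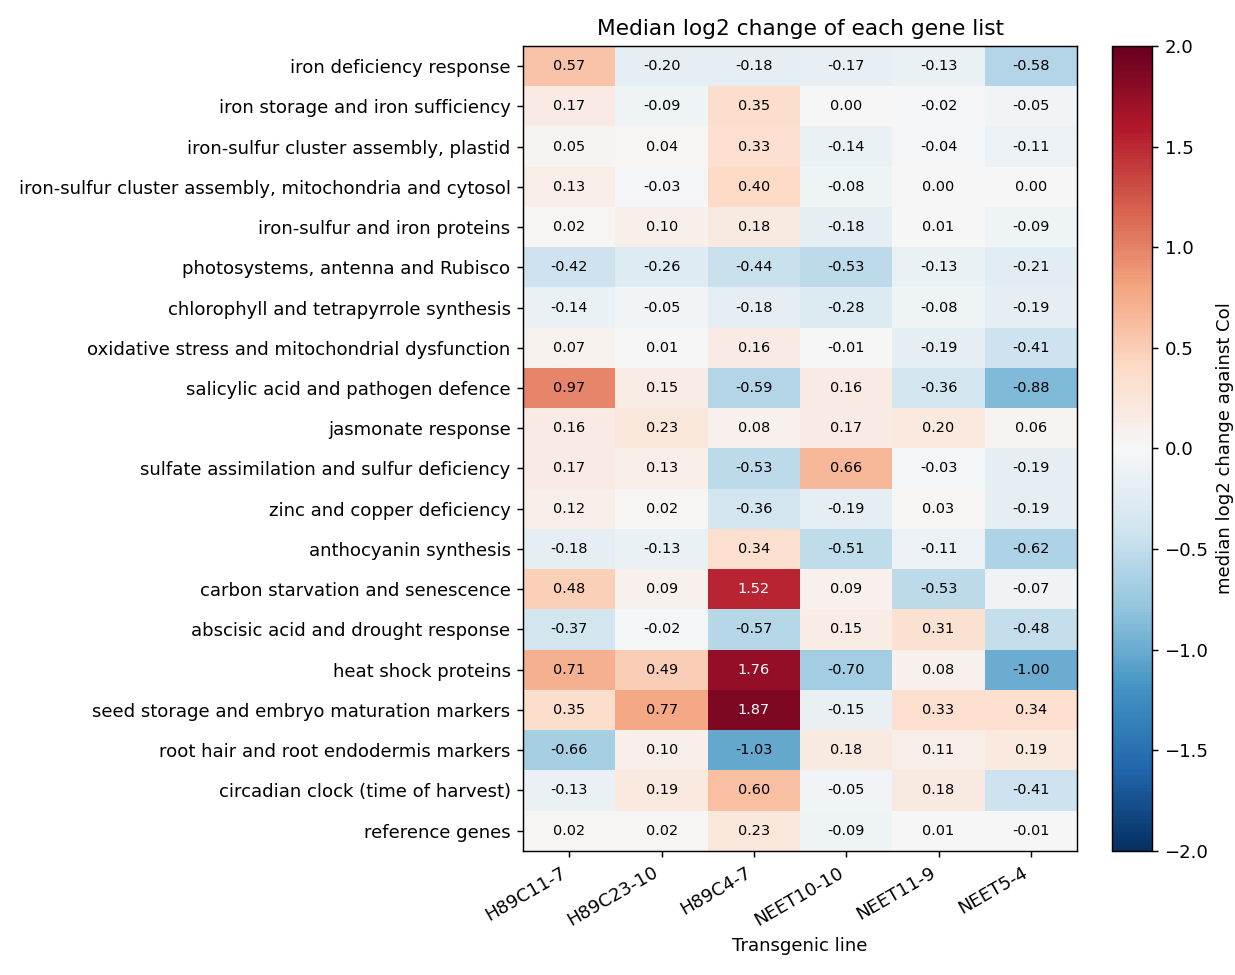
Median log2 change against Col of each of the 20 gene lists in the 6 lines. The photosystem list is below 0 in every line, from -0.53 in NEET10-10 to -0.13 in NEET11-9, and the heat shock list reaches 1.76 in H89C4-7.

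The mean of the NEET lines differed from Col in 5293 genes (2537 higher, 2756 lower; limma). In all 3 lines 536 genes changed the same way (253 higher, 283 lower). Independent lists would share 20.5 and 33.1, and simulated unchanged groups, which give almost no calls, shared 0 on average. As for H89C, neither value shows how many shared calls the Col libraries add. The shared count was 325 without NEET11-9 replicate 2, 345 without its replicate 3, 867 without Col replicate 2 and 2492 in the pair of lines left when NEET11-9 was removed. With the line as a random block limma called 0 genes, with 315 at an unadjusted p under 0.05. Without that block edgeR and DESeq2, run on libraries, called 5334 and 4800.

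H89C lines were compared with NEET lines to set the altered protein against the unaltered one, although NEET11-9 had AtNEET within the range of Col. On line means, 3 against 3, camera with the preset correlation called heat shock, seed storage, iron-sulfur and carbon starvation genes higher in the H89C lines and root markers lower. With an estimated correlation each of these calls was lost (adjusted p = 0.561 each), and no single gene passed the test. Without NEET11-9 limma again called 0 genes, the carbon starvation call ended (camera adjusted p = 0.135), and the others stood with the preset correlation but not with an estimated one (adjusted p = 0.599 each). Seed storage members went both ways, 7 higher and 5 lower. SESA2 came nearest, at log2 4.54 ± 0.45 (limma adjusted p = 0.187), with 23.5 to 40 in the H89C lines and at most 1.02 in the NEET lines, followed by CRU3 at log2 5.69 ± 0.66 (adjusted p = 0.275). Other members with the smallest p of their lists were SAG13 at log2 4.19 ± 0.96, DIN2 at 4.49 ± 1.16, AOX1D at 3.48 ± 0.86, S8H at 3.10 ± 0.76, HSP17.6II at 2.61 ± 0.67, ALD1 at 2.64 ± 0.53, SUFE2 at 1.09 ± 0.32, FD1 at 0.76 ± 0.20, PORA at -2.04 ± 0.75 and TIP2;3 at -2.03 ± 0.56, each with a limma adjusted p of 0.438. AtNEET itself differed by log2 -0.67 ± 1.83 (adjusted p = 0.872).

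All 13 plastid iron-sulfur assembly genes, 16 of 17 in mitochondria and cytosol and 23 of 26 iron-sulfur and iron proteins were higher in the H89C mean than in the NEET mean. Their medians were log2 0.27, 0.23 and 0.19, and camera gave adjusted p = 4.11e-04, 4.51e-04 and 4.11e-04, but adjusted p = 0.561 for each with an estimated correlation. Heat shock genes were higher in 8 of 8 (median log2 1.72, camera adjusted p = 4.31e-05; 6 called adjusted over the list alone) and root markers lower in 13 of 14 (median log2 -0.78, camera adjusted p = 2.57e-05); each had adjusted p = 0.561 with an estimated correlation. Iron deficiency genes had a median of log2 0.47 with 26 of 36 positive (camera adjusted p = 0.00371, adjusted p = 0.561 with an estimated correlation). IMA1 at log2 1.37 ± 0.41, BTS at 0.85 ± 0.32, bHLH39 at 0.83 ± 0.40, bHLH100 at 0.88 ± 0.63, bHLH101 at 0.51 ± 0.67, bHLH38 at 0.44 ± 0.58, FRO2 at 0.50 ± 0.42, FER1 at 0.47 ± 0.57, FER4 at 0.31 ± 0.13, FER3 at 0.24 ± 0.11, FIT at -0.22 ± 0.22 and IRT1 at 0.01 ± 0.42 had adjusted p from 0.438 to 0.988.

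Camera with the preset correlation also gave calls for oxidative stress (median log2 0.40, adjusted p = 0.00159), salicylic acid (0.77, 4.51e-04), anthocyanin (0.54, 0.0104), carbon starvation (0.60, 0.0188), abscisic acid (-0.31, 0.0362), photosystems (-0.09, 0.0362) and seed storage (0.86, 0.0415). With an estimated correlation these had adjusted p = 0.561, except photosystems with adjusted p = 0.707. Without NEET11-9 the photosystem (camera adjusted p = 0.699) and abscisic acid (0.247) calls ended too, and the clock list was called (0.0255; adjusted p = 0.599 with an estimated correlation). Adjusted over the list alone, 2 salicylic acid genes, 1 jasmonate gene (VSP1, log2 0.91 ± 0.20), 2 carbon starvation genes (SAG13 and DIN2), 5 seed genes higher and 3 lower were called, and 0 in the lists not named here or under heat shock. The clock list (median log2 0.30, camera adjusted p = 0.0646), iron storage (0.27, 0.155), sulfate (-0.26, 0.256), reference genes (0.08, 0.31), chlorophyll synthesis (median 0.06, mean -0.03, 0.335), zinc and copper (-0.02, 0.986) and jasmonate (median -0.06, mean 0.02, 0.986) were not called.

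Over all genes limma called 0 between the constructs on line means, with 2350 at an unadjusted p under 0.05. On reads summed per line edgeR called 0 with 2222 at an unadjusted p under 0.05, and DESeq2 called 225 with 3063. Line means of the constructs did not overlap in 4757 genes, which is 23%. For a single gene chance gives 10% with 3 lines against 3. Genes are not independent, so the share in 1 split of the lines can lie far from 10%. It was not counted in other splits, so an excess was not tested. With libraries as replicates limma called 12856, and with the line as a random block 926 (4137 at an unadjusted p under 0.05). Without the filter on low values 1 gene was called, PDF1.3, a plant defensin gene noticed after the test, with 7.8, 6.88 and 7.9 in H89C11-7, H89C23-10 and H89C4-7, 0.29 in NEET10-10 and 0 in NEET11-9, NEET5-4 and Col.

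The changes of the 2 constructs against Col overlapped in part. Genes higher in both means numbered 1292, with 659 for independent lists, genes lower in both 1125 (657 for independent lists), and 996 went opposite ways. The correlation of log2 changes across genes, which are not independent replicates, was 0.20, below the 0.75 that shared controls alone gave in unchanged groups, and the covariance was 0.030 against 0.0153. Of the 1077 genes higher in all 3 H89C lines 83 were higher in all 3 NEET lines, and of the 885 lower 79 were lower.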

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

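Differences between lines were sought among the iron genes fixed by name and the gene lists. An item was picked where 2 lines of 1 construct were called in opposite directions against Col. Their difference also had to pass a limma or camera test. Over all genes this test removed none, as with 211 of 211 between H89C11-7 and H89C23-10. For each item and construct 1 pair of lines was kept, the one with the largest difference. The differences given below are therefore the largest among the pairs that met the rule. Differences without opposite calls were left out, such as the defence list in NEET10-10 against NEET5-4 (median log2 1.17, camera adjusted p = 2.2e-08). The tests for H89C4-7 and for the resemblance of NEET11-9 and NEET5-4 were chosen only after the result was seen. The same holds for the stretch of chromosome 2 reaching AT2G19650.

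Between H89C lines, the iron uptake regulators were higher in H89C11-7. The log2 difference was 2.33 for bHLH100 (limma adjusted p = 2.65e-14), 2.13 for bHLH38 (7.62e-11) and 1.9 for bHLH101 (3.29e-13), each between H89C11-7 and H89C23-10, and 1.51 for bHLH39 (5.47e-13) between H89C11-7 and H89C4-7. FRO2 was higher in H89C11-7 than in H89C23-10 by log2 1.34 (adjusted p = 1.19e-08), while FIT was lower in H89C11-7 than in H89C4-7 by log2 -0.85 (9.86e-07). FER1 was lower in H89C23-10 than in H89C4-7 by log2 -2.13 (1.19e-21). Over the iron deficiency list H89C11-7 exceeded H89C23-10 by a median of log2 0.86 (camera adjusted p = 8.24e-24, adjusted p = 1.1e-05 with an estimated correlation).

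Between NEET lines, NEET10-10 exceeded NEET5-4 by log2 1.98 for bHLH101 (limma adjusted p = 1.75e-14), 0.85 for BTS (6.03e-14) and 0.70 for FER1 (1.54e-11). Sulfate assimilation genes were higher in NEET10-10 than in NEET5-4 by a median of log2 1.06 (camera adjusted p = 3.94e-10, adjusted p = 1.15e-04 with an estimated correlation). Carbon starvation genes were higher in NEET10-10 than in NEET11-9 by 1.15 (6.11e-05; adjusted p = 0.0035 with an estimated correlation), and abscisic acid genes in NEET11-9 than in NEET5-4 by 0.70 (3.45e-14; adjusted p = 8.12e-04 with an estimated correlation).

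H89C4-7 had more genes called than any other line. If library depth were the cause, the excess should vanish with equal reads, but with every library thinned to 8.24 M reads H89C4-7 had 11849 genes against 5572 in the next line, a ratio of 2.13. With trends on gene length and GC content removed the ratio was 1.72 (13569 against 7899), and NEET10-10, with more AtNEET, had 0.46 of the genes of H89C4-7, which argues against depth, against length and GC bias, and against the AtNEET level whatever the construct. Within the H89C lines the count did follow AtNEET, with levels of 1299, 2380 and 16100 and 4568, 7813 and 13783 genes in H89C23-10, H89C11-7 and H89C4-7. The dose of the altered form therefore stays open, as do the insertion site, culture and time of harvest of H89C4-7, and none of these was tested. The clock list, fixed with the time of harvest in mind, had 9 of 11 genes up and 0 down in H89C4-7. Camera gave it an adjusted p of 0.00349 with an estimated correlation.

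NEET11-9 and NEET5-4 shared log2 changes (r = 0.67, covariance 0.128) although AtNEET was near the Col level in NEET11-9. Shared Col libraries would give the simulated covariance, and the observed one was 8.4 times that. Had NEET5-4 plants been labelled NEET11-9, AtNEET would be high in those libraries, but the highest of them reached 1.86% of the NEET5-4 mean. Raised AtNEET transcript as the biological cause would make NEET10-10 resemble NEET5-4 as much, and the covariance of that pair was 0.48 of the one seen here. All 3 are argued against, and a shared growth batch, which the labels do not record, remains possible.

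In NEET5-4, neighbouring genes on chromosome 2 between 8485991 and 8495892 (9.9 kb) had few reads. AT2G19620 (NDL3) was at 0.7%, AT2G19640 (ASHR2) at 0.2% and AT2G19650 at 4.4% of the median of the other lines. The nearest well-measured genes on either side, AT2G19600 and AT2G19660, were at 92% and 88.2%. AT2G19610, between AT2G19600 and AT2G19620, had 0.3 in NEET5-4 and 3 to 5.8 elsewhere, too few reads to decide. Silent genes placed at random fell within 3 neighbouring genes in a share of 0.0024 of 10000 placements. AT2G07245 and AT2G19630 both lie between AT2G19620 and AT2G19640, so this pair is farther apart than the pairs counted. The share is therefore that of a closer event and does not decide about chance here. The test of a lost stretch set beforehand needed the next measured gene on each side above 50%, which AT2G19650 was not, and AT2G19630 between the silent genes, at 0 in NEET5-4, is too weakly expressed in every line to decide. For a stretch reaching AT2G19650 the value of 4.4% had been seen before the test and decides nothing, and with 19.8 counts left there, and no measure of how many reads a deleted gene would still collect, loss of the stretch and local silencing both stay open.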

How the results depend on the processing

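The alternatives and the tests added later, which are the thinning, the length and GC trends, the iron list without H89C11-7, the NEET results and list tests without NEET11-9, the list counts without each library or line and the differences between lines for every list, were chosen only after the result was seen. Of the gene counts 220 alternatives stayed within 1.5 times the main count and 29 did not. Of the counts of list members 3043 stayed within 1.5 times and 384 did not. Of values of named genes 5239 kept direction and side of the threshold, 422 fell short, 70 newly passed and 32 turned. TMM, other pseudocounts and filters and edgeR moved no count against Col by over 1.5 times. Leaving out 1 library gave 6470 to 7613 genes in H89C11-7, 3288 to 4853 in H89C23-10, 12923 to 13410 in H89C4-7, 5194 to 6177 in NEET10-10, 1370 to 2875 in NEET11-9, 5246 to 6645 in NEET5-4, 9388 to 10121 in the mean H89C, 4093 to 5553 in the mean NEET, 1521 to 2138 in all 3 H89C lines, 325 to 867 in all 3 NEET lines and 0 to 0 between constructs. Libraries of the same number were not paired (mean correlation 0.001, 0 of 63 pairs above 0.1), and the replicate number as a block gave 10321 and 5310 genes in the means.

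With a log2 limit of 1 the counts were 865, 289 and 3286 in H89C11-7, H89C23-10 and H89C4-7, 387, 327 and 816 in NEET10-10, NEET11-9 and NEET5-4, 793 and 303 in the means and 87 and 34 in all 3 lines. Thinned to equal depth, which leaves fewer reads, they were 2901 in H89C23-10, 1337 in NEET11-9, 3329 in the mean NEET, and 1161 and 274 in all 3 lines. Without NEET11-9 the remaining NEET lines shared 2492. Between constructs the count was 1 with no filter, 225 with DESeq2, 926 with the line as a random block and 12856 with libraries as replicates; the random block gave 9 and 0 in the means. With an estimated correlation 8 of 32 list calls remained.

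Values that turned, as log2, follow, and the cause was not tested. IRT1 between constructs, 0.015 in the main test, ranged from -0.065 to 0.060 with 1 library left out. It was -0.003 with TMM, -0.008 with length and GC trends removed, -0.010 and -0.012 without H89C11-7 or H89C23-10 replicate 3, -0.065 without NEET10-10 replicate 1, -0.001 without NEET11-9 replicate 2, -0.028 without NEET5-4 replicate 1, -0.381 without H89C11-7 and -0.303 without NEET10-10. Without H89C11-7 the mean H89C of bHLH39 was -0.371, bHLH100 -0.435 and FIT 0.112, and between constructs bHLH38 was -0.257, bHLH101 -0.114 and FIT 0.007. Without H89C23-10 CCA1 was 0.013, bHLH38 0.186, bHLH101 0.241, FRO2 0.209 and, between constructs, AtNEET 0.085. Without H89C4-7 FER1 was -0.146, PORB 0.020, APR1 0.237, bHLH38 0.145, bHLH101 0.211 and, between constructs, FER1 -0.221. Without NEET10-10 the mean NEET of SHM7 was -0.012, APR3 -0.226 and FER1 -0.133, and AtNEET between constructs 0.580; without NEET5-4 RD29A was 0.168 and AtNEET between constructs 0.154.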

Other observations

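Genes in the next 3 paragraphs were picked after their values were seen; the tests of other splits of the samples were set beforehand, except the comparison of unadjusted p between constructs, which was chosen only after the result was seen.

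The genes next to MRN1 in the marneral cluster rose too. CYP705A12, a cytochrome P450 of that pathway, went from 51.6 ± 17.7 in Col to 318 ± 24.5 in H89C23-10, 117 ± 11.9 in H89C11-7 and 117 ± 6.62 in H89C4-7, and to 139 ± 5.99, 91 ± 8.95 and 105 ± 8.59 in NEET10-10, NEET11-9 and NEET5-4 (SD, n = 3; limma adjusted p at most 4.8e-04 in each line). CYP71A16, which oxidizes marneral, went from 146 (134 to 153) to 373 ± 64.4 in H89C23-10 and to 312 ± 12.1, 239 ± 26 and 283 ± 41.3 in the NEET lines, but was 146 ± 25 in H89C11-7 and 156 ± 2.16 in H89C4-7, where it was not called.

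CYP716A2, AT5G36130 and SESA1 had reads in every H89C line and almost none elsewhere. CYP716A2, a triterpene-oxidizing P450, was 0 in Col and 19.6 ± 8.6, 16 ± 4.67 and 24.6 ± 1.9 in H89C11-7, H89C23-10 and H89C4-7, against 0.585 ± 0.507 in NEET10-10 and 0 in the other NEET lines. AT5G36130 was 0 in Col and all NEET lines and 6.77 ± 3.44, 7.18 ± 2.67 and 11.7 ± 1.87 in the H89C lines in that order. The seed albumin SESA1 was 0 in Col and the NEET lines and 14.9 ± 16.3, 7.48 ± 6.42 and 52.2 ± 24 in the H89C lines. CRU3, a seed cruciferin, also had reads in Col, 24 ± 34.9 with libraries from 2.45 to 64.3, and was up to 188 ± 77.4 in H89C4-7 and at most 2.33 ± 1.22 in the NEET lines.

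Besides the 9.9 kb stretch of chromosome 2, NEET5-4 had few reads on CYP71A12, which lies elsewhere on that chromosome at 13099486. This enzyme of indole defence compounds was at 6.58 against a median of 1590 in the other lines. Reads in NEET5-4 were also few on GLP9 at 25.2 against 1380 and on AT5G48430 at 9.26 against 440. The same held for AT1G26380 at 1.61 against 385 and AT1G14550 at 3.65 against 270. H89C4-7 had 4.2 on HAK5, a high-affinity potassium transporter, against 278.

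Other splits of the samples were counted in fits of their own. For each line against Col, 1 of the 10 splits into 3 and 3 libraries, the real one, gave as many genes as the real one (5664 in H89C11-7, 2430 in H89C23-10, 12276 in H89C4-7, 2497 in NEET10-10, 865 in NEET11-9, 4295 in NEET5-4, at most 0 in any other), and 10 splits are too few for a share under 0.05. For the mean of the H89C lines 3 of 100 splits did so (835 real, up to 12086 in a split that sets H89C4-7 apart), and for the mean of the NEET lines 3 of 100 (124 real, up to 2724 in one that sets NEET5-4 apart). For genes shared by all 3 lines it was 1 of 100 in each construct (1798 against at most 31, and 282 against at most 10). Between constructs all 10 of 10 splits of the lines reached the real count of 0, and the real split had 2350 genes at an unadjusted limma p under 0.05 against at most 1084 in the others.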
